A study of Mus musculus with 16 samples.

How the data were processed

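Spinal cord RNA of male mice aged 50 days was measured in 16 libraries, 8 from mice of the SOD1-G93A model of amyotrophic lateral sclerosis (ALS) and 8 from wild-type mice. Per the labels' protocols, tissue was homogenised in a phenol-based reagent, ribosomal RNA was depleted, and the RNA was digested with RNase R, an exonuclease that degrades linear RNA and leaves most circular RNA (circRNA) intact. Adapters were ligated to cDNA, the second strand was removed and the first strand was amplified by PCR, per the labels' protocols. Per the submitters' processing notes, FastQC and HTSeq were among the tools used and the genome build was GRCm38.p6. The circRNA caller, the aligner and the filters on circRNAs are not given in the sources used here.

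The authors deposited a single table of read counts, with a circRNA identifier per line and a column per library, and no normalisation. It held 24411 circRNAs. The values were whole numbers of 0 or of 2 and above, with 0 values of 1, and every circRNA had at least 16 counts in total and was above 0 in at least 2 libraries, so low counts had been removed before deposit. A last line without an identifier repeated the total of the first library, 581711 counts, and was left out of library sizes and tests. Apart from the 16 library columns, 0 columns of per-sample values were present. Beside the line of mmu_circ_db_0000216, the authors' deposited table also held a pair of stray values, 515.875 and 632.5, which equal that circRNA's mean counts in the SOD1-G93A and wild-type libraries.

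Identifiers were of 2 forms, with and without the letters db. The files do not pair them with genes or positions, and 0 identifiers matched the mouse gene tables used for names. For that reason the planned tests of host genes, of isoform usage within a host gene and of gene lists were not run, the transcript of the transgene was not looked up, and circRNAs are given by identifier. The rule for named circRNAs was fixed before the data were examined: those past the threshold with the largest change in each direction, filled up with the smallest unadjusted p to 5 per direction, and the 5 with the highest mean abundance. Of the first part, the identifiers of 1 lower and 2 higher circRNAs are printed, and the others are given as ranges, because the files do not pair identifiers with genes.

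Libraries were grouped by the genotype in the labels. The design text gives 8 mice per genotype, and each label names a separate numbered library. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust dispersions, filterByExpr (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment at 0.05. This left 5489 circRNAs holding 84.8% of the counts. Fold changes are SOD1-G93A over wild type, abundances are CPM, counts scaled to the TMM-adjusted sum over the tested circRNAs of a library, and intervals of fold changes are at the 95% level. Those intervals come from the edgeR fit and include the spread between libraries. No limit is given for a count of 0, because the deposited table holds no values of 1 and a 0 can stand for a removed low count. PCR copies are not independent molecules.

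Totals and numbers of detected circRNAs were compared with a 2-sided exact permutation test over all 12870 relabellings of the libraries, whose smallest possible p is 0.000155. For detection, each library was thinned at random to 238428 counts, the smallest total. Because the deposited values hold no 1, thinning makes values of 1 in deep libraries that shallow libraries cannot hold, so detection from 1 count still moves with depth; detection from 5 counts, planned as an alternative, is given beside it. Separation of the genotypes was the share of variance of log2 CPM (prior count 2) between genotypes over the 500 most variable circRNAs. Libraries were checked for duplicates by chi-square over the 1418 circRNAs with a mean count of 50 or more. The smallest chi-square per degree of freedom over 120 pairs was 5.57, so no library was a copy of another within sampling noise.

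The edgeR script was tested on simulated data for SOD1-G93A against wild type, with 5489 circRNAs and 200 of them changed in each of 5 rounds. It called 11.2% of those changed 1.5-fold, 38.8% of those changed 2-fold, 69.2% at 3-fold and 74.8% at 4-fold, and 0.0492% of the unchanged ones. Alternatives were other normalisation factors, DESeq2 1.42.0, limma 3.58.1 with voom and sample quality weights, and other low-count filters. Others were a block from the replicate numbers, a covariate from the library numbers, a surrogate variable from sva 3.50.0, and leaving out each library. Permutations and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.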

Results

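Circular RNAs, closed transcripts formed when a downstream splice site joins an upstream one, were profiled in the spinal cord of 50-day-old male mice. The SOD1-G93A mouse carries a mutant form of superoxide dismutase 1 linked to ALS. The 8 SOD1-G93A and 8 wild-type libraries held 6434755 counts over 24411 circRNAs, from 238428 to 673963 counts per library. Of these circRNAs, 4993 (20.5%) were above 0 in all 16 libraries, and the median circRNA had a mean count of 3.25. Counts were spread over many species: 686 circRNAs held 50% of all counts, and the 5 most abundant held 3.33%.

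The first comparison asked which circRNAs differed in abundance between the genotypes. With the edgeR quasi-likelihood test, 0 of 5489 circRNAs were higher and 0 were lower in SOD1-G93A at an adjusted p under 0.05, and the smallest adjusted p was 0.906. The smallest adjusted p was 0.242 with limma-voom, 0.299 with edgeR without SOD1-G93A replicate 3 and 0.449 without wild-type replicate 6. At an unadjusted p under 0.05 there were 193 circRNAs, 89 higher and 104 lower, where 274.4 would fall under it by chance. The 193 were 3.52% of the circRNAs tested. DESeq2 tested 24407 circRNAs, called 2 lower and had 592 (2.43%) at an unadjusted p under 0.05. On the 5489 circRNAs, limma-voom called 0 and had 298 (5.43%). The fold changes centred on 0, with a median of 0.0087 on the log2 scale and a 5th to 95th percentile of -0.49 to 0.51. TMM factors bring the centre near 0, so it cannot show whether circRNAs as a whole changed.

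The circRNA with the smallest p was mmu_circ_db_0000216, at 1494 ± 116 CPM in SOD1-G93A and 1864 ± 109 CPM in wild type (SD, n = 8 each). Its log2 fold change was -0.32 (SE 0.073, 95% interval -0.47 to -0.17), and 8 of 8 SOD1-G93A libraries lay below the wild-type median. It did not pass with edgeR (adjusted p = 0.906) and passed with DESeq2 (adjusted p = 0.0180, log2 fold change -0.32, SE 0.066). Over all alternatives its adjusted p ranged from 0.0180 to 1. In the other direction, mmu_circ_0062936 averaged 872 ± 167 CPM in SOD1-G93A and 568 ± 144 CPM in wild type (SD, n = 8 each), with a log2 fold change of 0.62 (SE 0.159) and 7 of 8 SOD1-G93A libraries above the wild-type median. Its edgeR adjusted p was 0.906, and over all alternatives it ranged from 0.00525, with edgeR without a low-count filter, to 1. For mmu_circ_0074533 the values were 116 ± 33.4 and 64.1 ± 27.8 CPM (SD, n = 8 each), a log2 fold change of 0.87 (SE 0.250) with an edgeR adjusted p of 0.999, and 8 of 8 SOD1-G93A libraries were above the wild-type median. By the same rule, 4 further circRNAs with lower values had log2 fold changes of -0.66 to -0.38 and unadjusted edgeR p of 0.000681 to 0.000991, each with 8 of 8 SOD1-G93A libraries below the wild-type median. A further 3 with higher values had log2 fold changes of 0.65 to 1.56 and unadjusted edgeR p of 0.00191 to 0.00248. For each of them, 6 to 8 of 8 SOD1-G93A libraries lay above the wild-type median. With edgeR, 0 of these 7 passed the adjusted threshold. All circRNAs of this paragraph were picked for a small p in these same libraries. The counts of libraries above or below the median are therefore not separate support.

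A scarce circRNA outside the filtered test, mmu_circ_db_0001146, was singled out after its values were seen. It had 0 counts in 8 of 8 SOD1-G93A libraries and 9 to 18 counts in 6 of 8 wild-type libraries. No fold is given, because low counts had been removed from the table. Its adjusted p was 0.0180 with DESeq2 and 0.000517 with edgeR without a low-count filter. Presence in 6 or more libraries of 1 genotype and in 0 of the other was found for 14 circRNAs, against a median of 17 over relabellings (exact permutation p = 0.780).

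**Figure D1:**
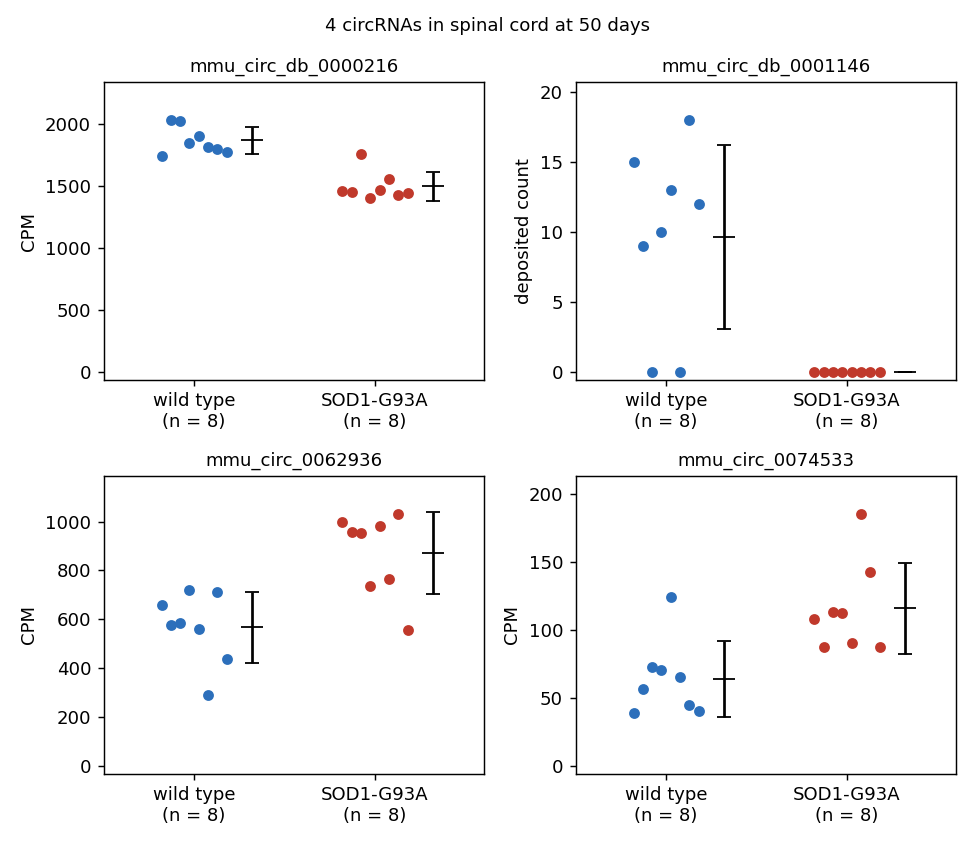
Points are single libraries of wild-type and SOD1-G93A spinal cord, and bars show the mean ± SD (n = 8 each); the vertical axes give CPM, or deposited counts for mmu_circ_db_0001146. All 8 SOD1-G93A libraries lie below the wild-type median for mmu_circ_db_0000216, and all 8 are at 0 counts for mmu_circ_db_0001146.

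Of the 5 most abundant circRNAs, 0 passed the edgeR test, and 0 had an unadjusted p under 0.05; DESeq2 and limma-voom also called 0 of them. The most abundant, mmu_circ_db_0000723, was at 10080 ± 2949 CPM in SOD1-G93A and 8587 ± 4577 CPM in wild type (SD, n = 8 each), with a log2 fold change of 0.23 (95% interval -0.48 to 0.94). That value moved to 0.093 without wild-type replicate 5, to 0.12 without wild-type replicate 4 and to 0.44 without wild-type replicate 2, and to 0.15 without SOD1-G93A replicate 3; it turned to -0.036 without both wild-type replicates 4 and 5 and to -0.0053 with 1 surrogate variable. For mmu_circ_db_0000595 the interval was -0.12 to 0.15, for mmu_circ_db_0001125 it was -0.26 to 0.054 and for mmu_circ_db_0001311 it was -0.17 to 0.30. The log2 fold change of mmu_circ_db_0001394 was -0.29 (95% interval -1.49 to 0.92), and 1 SOD1-G93A library, replicate 6, had 8 counts of it against 1801 to 4469 in the other libraries. Without that library the log2 fold change was -0.10, and with limma-voom on all libraries it was -0.99.

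Precision depended on abundance. The 95% interval lay within 2-fold in either direction for 3639 of the tested circRNAs (66.3%) and within 1.5-fold for 1370 (25.0%). Among the 1830 most abundant, the median standard error was 0.18 on the log2 scale and 94.2% were within 2-fold, while among the 1830 least abundant the median was 0.42 and 29.6% were within 2-fold.

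**Figure D2:**
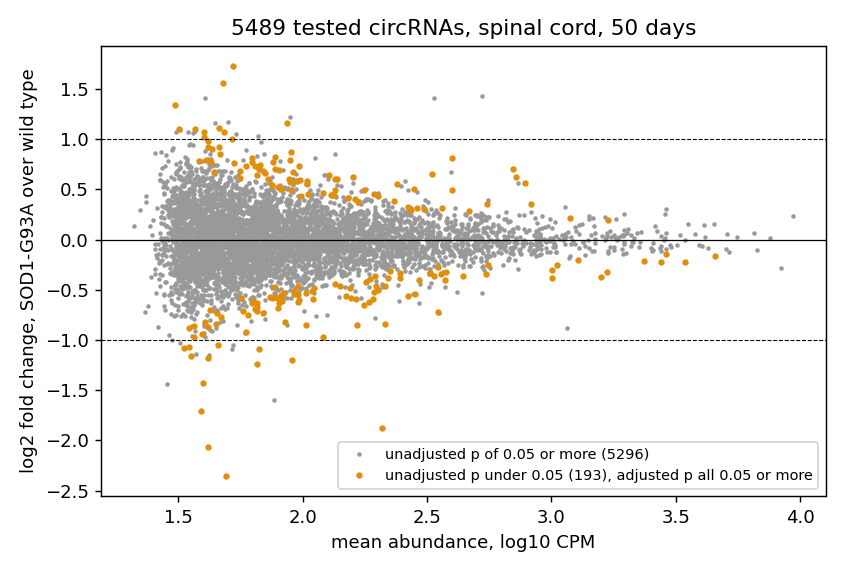
Each point is a tested circRNA, with its mean abundance (log10 CPM) on the horizontal axis and its log2 fold change of SOD1-G93A over wild type on the vertical axis; dashed lines mark 2-fold. The 193 circRNAs at an unadjusted p under 0.05 lie on both sides of 0, and the spread narrows with abundance.

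The second comparison asked whether the total count or variety of circRNAs differed. Totals also depend on sequencing depth, so they do not measure the yield of circRNAs per tissue. Total counts were 404220 ± 105653 in SOD1-G93A and 400125 ± 143542 in wild type (SD, n = 8 each, exact permutation p = 0.947). After thinning to equal totals, 15185 ± 1204 circRNAs were detected in SOD1-G93A and 14683 ± 1935 in wild type (SD, n = 8 each, exact permutation p = 0.548). From 5 counts upward, the numbers were 7737 ± 82.7 and 7724 ± 57.4 (SD, n = 8 each, exact permutation p = 0.723). The identifiers with db took 42.9 ± 0.191% of counts in SOD1-G93A and 42.8 ± 0.362% in wild type (SD, n = 8 each, exact permutation p = 0.841).

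**Figure D3:**
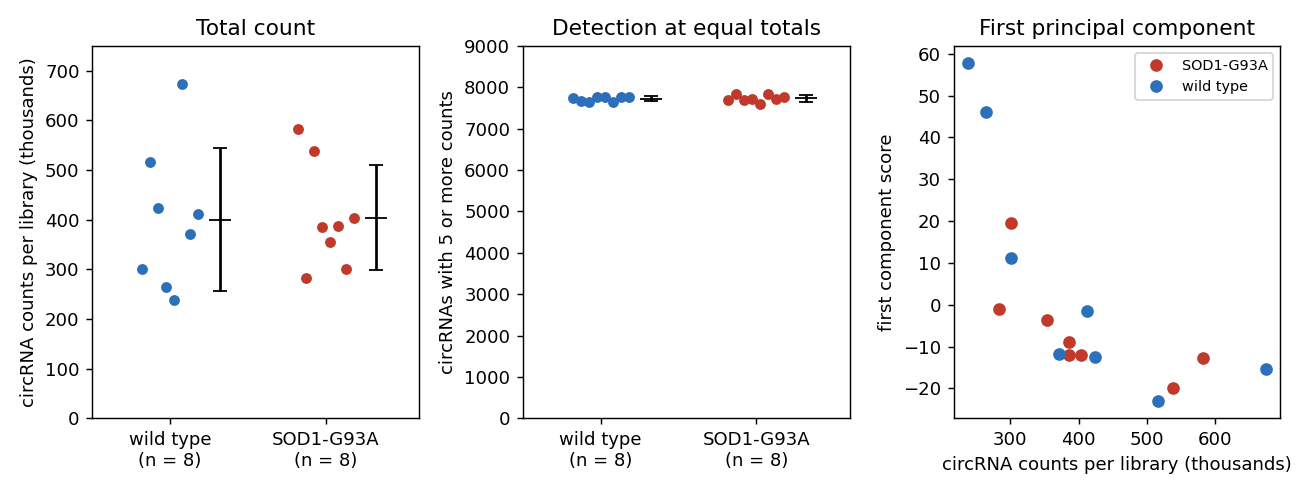
The left and middle panels give the total count and the circRNAs with 5 or more counts after thinning to equal totals, with a point per library and the mean ± SD (n = 8 each); the right panel sets the first component score against the total count. Totals overlap between genotypes, and wild-type replicates 4 and 5 score 46.0 and 57.8, above the other libraries.

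The third comparison asked whether genotype separated the libraries as a whole. Genotype held 7.63% of the variance of the 500 most variable circRNAs, against a median of 6.40% over relabellings (exact permutation p = 0.169). The first principal component of all tested circRNAs held 18.7% of the variance and did not differ between genotypes beyond the spread between libraries (exact permutation p = 0.309). It followed library depth, with a Pearson r of -0.713 with the total count (permutation p = 0.0031, adjusted 0.0031 over 4 relations) and a Spearman rho of -0.915 (permutation p = 2e-05, adjusted 4e-05). Without the 2 libraries farthest from the median total, wild-type replicate 6 and SOD1-G93A replicate 1, r was -0.819. Wild-type replicates 4 and 5, with the highest scores, were kept in that value. Within SOD1-G93A rho was -0.929, and within wild type it was -0.952.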

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

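Values far from the rest of their group were sought in 20 quantities, which makes 40 groups of 8 libraries; chance marks about 5% of groups, or 2 of these, and 5 were found. The tests of the first component by genotype and with values of 1 removed or abundant circRNAs alone were chosen after the result was seen, as was the test of the 0 calls against other splits.

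A wild-type library, replicate 5, had 42.1% of its counts in identifiers with db, where the other 7 lay from 42.7% to 43.3%. The same library held mmu_circ_0074533 at 124 CPM against 38.7 to 72.6 in the others of its group. A SOD1-G93A library, replicate 3, held mmu_circ_db_0000216 at 1759 CPM against 1405 to 1557 in the others. Wild-type replicate 4 held 466 CPM of a further circRNA with a small unadjusted p, against 277 to 363 in the others. SOD1-G93A replicate 6 held mmu_circ_db_0001394 at 24.3 CPM, where the other 7 lay from 7347 to 10062.

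Chance could not be excluded for the comparison of genotypes. At an unadjusted p under 0.05, 33 of 100 splits of the 16 libraries, the real one included, gave at least the real 193 circRNAs, and the highest other count was 505. For calls past the adjusted threshold the splits decide nothing, since each of the 100 must reach the real 0; the highest other count was 1.

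Wild-type replicates 4 and 5 stood far out on the first component, with scores of 46.0 and 57.8, and they were the smallest libraries, at 264371 and 238428 counts. Sampling noise at lower depth as the whole cause was argued against, because after thinning to equal totals and setting values of 1 to 0 they scored 40.3 and 47.8 against 20.1 for the next library, with 378 and 414 tested circRNAs at 0 against 84 to 226 elsewhere, and the thinned component still followed the original total (Spearman rho -0.865, permutation p = 7e-05). Over circRNAs with a mean count of 50 or more the gap was small, at 15.4 and 17.5 against 11.7, so it rested at least in part on scarcer circRNAs. Genotype as the whole cause was argued against, because 4 wild-type libraries scored below the median SOD1-G93A library. That overlap cannot exclude an effect present in only part of the mice. Fewer independent molecules behind the counts, which thinning cannot equalise, may remain, and this was not tested.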

How the results depend on the processing

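The alternatives without wild-type replicates 4 and 5, without all-or-none circRNAs, with 6 or more libraries and with thinned values of 1 set to 0 were chosen after seeing the data. The count of 0 circRNAs past the threshold stayed at 0 with edgeR under other factors, a mean count filter, covariates and without those 2 libraries, with limma-voom, and from 0 to 0 over 16 leave-one-out fits (169 to 251 at an unadjusted p under 0.05). It was 2 with DESeq2 on 24407 circRNAs (592 unadjusted, 2.43%) and 2 with edgeR without a low-count filter on 24411 (902 unadjusted, 3.70%), against 3.52% of 5489 as reported, and the cause was not tested. The labels do not say whether equal replicate numbers mark paired mice, although the library numbers of equal replicates lie close together. Correlations between libraries of the same replicate number ran from -0.146 to 0.146. In each genotype, 2 of 8 libraries correlated best with their own number. Weak correlations cannot show that the mice were unpaired. With a replicate block, edgeR called 0 circRNAs (208 unadjusted), the total differed by 4095 counts (exact p = 0.984) and detection by 502 (exact p = 0.578). The separation was 14.8% of the variance left after centring within replicate numbers, against a median of 11.9% over relabellings (exact p = 0.148). This is a share of a smaller variance than the 7.63% without the block.

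Without wild-type replicates 4 and 5, the difference in total turned from 4095 to -45480 counts (exact p = 0.481) and in detected circRNAs from 502 to -377 (exact p = 0.555), which follows from leaving out the 2 smallest libraries. circRNAs detected in 1 genotype only numbered 14 when 6 or more libraries were required, against 181 with 4. Of the named log2 fold changes, 394 alternative values kept direction and side of the threshold, 2 passed it and 9 reversed, all near 0. With 1 surrogate variable the reversed values were -0.0053 for mmu_circ_db_0000723, -0.010 for mmu_circ_db_0000595 and -0.039 for mmu_circ_db_0001311; without the 2 libraries they were -0.036, -0.022 and -0.074; leave-one-out values ran from -0.019 to 0.047 for mmu_circ_db_0000595 and from -0.014 to 0.13 for mmu_circ_db_0001311. The log2 fold change of mmu_circ_db_0001394 was -0.53 with the replicate block, against -0.29. The cause was not tested. Other settings for host genes, isoform usage and gene lists were not run, because the files do not pair identifiers with genes. In simulation edgeR called 38.8% of 2-fold changes over all tested circRNAs. Intervals were wider for scarce circRNAs, and how much of that is depth and how much spread between mice was not separated.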

Other observations

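The search for all-or-none circRNAs, its stricter settings and the tests of drops in 1 library, of opposite partners, of presence within a genotype and of neighbouring identifiers were chosen after the results were seen; the test of presence within a genotype took the place of Fisher's exact test by genotype, which had been set first and is also given. Some circRNAs were present well above 0 in part of the mice and near 0 in the rest. Among 2023 circRNAs whose level where present predicts at least 20 counts in every library, 85 (4.20%) fell under 10% of that level in 1 or more libraries, 31 of them in 1 library and 54 in 2 or more. Of the 31, 23 dropped in a wild-type library, 17 of these in replicates 4 or 5, and 8 in a SOD1-G93A library. For example, mmu_circ_0050215 had 238 to 244 counts in 3 libraries and 0 in the other 13. Both mmu_circ_0075428 and mmu_circ_0075430 were at 0 in 4 wild-type libraries and at 66 to 212 and 102 to 438 counts in the other 12. With a stricter expected count of 30, 49 such circRNAs were found, and with a stricter level of 5%, 74.

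Sampling as the whole cause was argued against, because a negative binomial with 1 common dispersion of 0.137 gave 3.49 of the 284 drops (1.23%). Dispersions of single circRNAs were not used, so drops of highly variable circRNAs may be underestimated. Without wild-type replicates 4 and 5 the negative binomial gave 2.49 of the 236. For the 31 single drops it gave at most 11.3%, which argues against sampling as their whole cause too. In wild-type replicates 4 and 5, where single drops gather, it gave 0.408 and 0.593 drops against 8 and 9 single drops. Sampling stays open for some of the 31. Whether fewer independent molecules in those libraries added to their single drops was not tested. For reads passed to another circRNA of the table, 0 partners with the exactly opposite presence pattern were found. This cannot decide the question, because a circRNA that received such reads beside reads of its own would not show that pattern. Presence varied within a genotype for all 54 circRNAs absent in 2 or more libraries, which argues against the transgene as the whole cause. It leaves open an effect in part of the mice, since only absence in exactly 8 libraries could avoid such variation. Fisher's exact test by genotype left 0 at an adjusted p under 0.05, with 1 at an unadjusted p under 0.05. That test could exclude little, because even 4 absences all in 1 genotype give an unadjusted Fisher p of 0.0769. A candidate explanation is an inherited variant near the back-splice junction: the 4 pairs with identifier numbers within 2 of each other had presence patterns with a mean correlation of 0.947, against -0.0090 in 1077 other pairs (permutation p = 1e-05, the smallest that 100000 permutations can give). Whether libraries holding such a circRNA differ by carrying 1 or 2 copies is undecided: the coefficient of variation where present was 1.38 times that of matched circRNAs, but the matched ones had been chosen for having no drop. Over all tested circRNAs without db, 735 pairs of neighbouring numbers had a median correlation of abundance of 0.113, against -0.0052 in random pairs. Whether neighbouring numbers mean neighbouring positions is open, and circRNAs sharing a splice site would also share a pattern.

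Of circRNAs detected in 4 or more libraries of 1 genotype and in 0 of the other, 94 were found in SOD1-G93A and 87 in wild type. Their sum, 181, is close to the median of 177 over relabellings, and chance could not be excluded (exact permutation p = 0.437). Without wild-type replicates 4 and 5 the numbers were 168 and 57, and their sum of 225 stood against a median of 240 (exact permutation p = 0.592). With fewer wild-type libraries left, the rule is easier to meet in SOD1-G93A, so 168 and 57 cannot be compared directly.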
